A study of Homo sapiens with 45 samples.

How the data were processed

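The series holds 45 libraries from HEK293T cells, a human embryonic kidney line, in 15 groups of 3 replicates. Per the labels' protocols, cells were treated for 72 h with the solvent DMSO, with 30 µM BPK25 or with 0.5 mM IAA. Sonicated chromatin was immunoprecipitated with antibodies against CTCF, MBD2, MBD3 or TET1, which gave 36 libraries, and 9 libraries were made from input DNA. The labels' protocols give a gel selection of fragments from 200 to 500 bp. Groups were taken from the treatment and antibody named in the labels of each library. The labels do not name the protein that IAA acts on, and whether replicates came from separate cultures is not given in the sources used here.

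The values come from 12 deposited peak lists, 1 for each treatment and antibody, which the authors called on replicates 1 to 3 together against control libraries. Per the submitters' processing notes, the tools were FastQC 0.11.7, Bowtie2 2.3.4, SAMtools 1.9, MACS2 2.1.2, bedtools 2.25.0 and deepTools 3.5.0, and the genome build was hg19. The settings of the peak caller are not given in the sources used here. In each deposited list, the fold enrichment of a peak is a linear ratio of pileup to local background at its summit, as the authors' caller wrote it. The deposited lists also give the −log10 of the p-value and of the q-value of each peak, and the offset of its summit from its start. The fold and the significance of a peak are the authors' values and served only to describe, rank or filter peaks within a list. Signal tracks and read counts per library were not used here.

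Sub-peaks that share a start and an end were counted as 1 region, with the values of the sub-peak of largest −log10 p. A region counted as shared when it overlapped a region of another list by 1 bp or more. Shares carry 95% Wilson intervals, which cover counting over regions only and say nothing of the spread between cultures. The lists used here give 1 value per group although 3 libraries were made, so differences between treatments or antibodies were not tested. Chance overlap was measured on chromosomes 1 to 22 and X with 1000 circular shifts of a list within each chromosome, one-sided, with the furthest region end as the chromosome's length. Overlap was also measured for positions drawn 200 times, as many as the list held, from the regions of the other 3 antibodies in the same treatment. It was left out for CTCF under IAA, where the other lists held fewer positions than needed, and for the partners of CTCF in DMSO, where the positions would include the CTCF regions themselves and list lengths would fix the outcome. All lists of a treatment may share their input libraries as control, since the labels name 1 set of inputs per treatment.

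The depth of single libraries is unknown from peak lists. A relative depth per list was recovered from the deposited values, a step chosen after seeing the data. The fold enrichment was read as the pileup plus 1 over the local background plus 1, and the −log10 p as the Poisson upper tail of the pileup. Solved for whole pileups, all 51545 regions with a pileup under 100 fitted within 0.02% of their −log10 p or its rounding. With the p-values shuffled within a list, between 0.930% and 4.58% fitted in the 9 lists with at least 200 such regions. Regions with a −log10 p above 150 were left unsolved. The smallest local background of a list, its floor, was taken as the background of the whole genome, which grows with the number of sequenced fragments and their length. The pileups of DMSO regions were then thinned to the floor of a treated list to give the share expected past that list's least −log10 p. At regions shared by a pair of lists, the pileups were also compared with 1 constant ratio, given as the mean squared deviation over counting noise.

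The scripts were tested on simulated data. A simulated list with 60% of its regions at DMSO CTCF regions gave 60%, and one with 30% at DMSO TET1 regions gave 30%. All 1863 simulated pileups were recovered. Thinning to depths of 0.2 and 0.5 gave 79.4% and 92.6% expected against 79.2% and 92.8% drawn. The squared deviation was 0.908 for simulated lists with 1 constant ratio at DMSO CTCF regions, and 2.18 with a site-to-site SD of 0.3 on the natural log scale. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.

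Comparisons, alternatives and the rule for named regions were set before the data were examined, except where stated. Named regions lie on chromosomes 1 to 22 and X and have a −log10 q of 5 or more. They are the 2 DMSO regions of highest fold for each antibody and, for each treated list, the 2 of highest fold that overlap a DMSO region of the same antibody and the 2 that do not. The alternatives were a −log10 q of 5 or more, a fold of 5 or more, chromosomes 1 to 22 and X alone, an overlap of 50% of the shorter region, summits within 150 bp, leaving out regions shared by all 4 antibodies, and DMSO lists shortened to the treated length by highest −log10 q. Planned results on promoters, gene lists and sequence were not run, because the gene table at hand describes GRCh38 while the regions are in hg19, and coordinates were not converted. Regions are therefore named by position only.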

Results

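Genome occupancy of CTCF, MBD2, MBD3 and TET1 was measured by ChIP-seq in HEK293T cells treated with DMSO, BPK25 or IAA for 72 h. CTCF is a zinc finger protein of insulators and loop anchors. MBD2 and MBD3 are alternative subunits of the NuRD nucleosome remodelling and deacetylase complex, and TET1 oxidises methylated cytosine. The title of the series asks about NuRD and the chromatin environment at CTCF sites. The design therefore poses 2 questions, which regions the 4 proteins share in DMSO, and which regions remain listed under each treatment. Each treatment and antibody had 3 libraries, which the authors pooled before calling peaks, so every value below comes from 1 pooled list and has no replicate error.

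In DMSO, the lists held 17440 regions for CTCF, 15991 for MBD2, 10137 for MBD3 and 7211 for TET1. Under BPK25 they held 375, 510, 374 and 777 regions, and under IAA 595, 138, 95 and 100. The treated lists were thus 0.863% to 10.8% as long as the DMSO list of the same antibody, with TET1 under BPK25 the longest in proportion and MBD2 under IAA the shortest. Regions were narrow, with a median width of 252 bp for CTCF and 235 bp for TET1 in DMSO, and the DMSO CTCF regions covered 4.81 Mb. The authors' fold enrichment had a median of 4.31 for CTCF, 4.54 for MBD2, 3.84 for MBD3 and 3.37 for TET1 in DMSO. In the BPK25 lists the median fold was 4.73, 4.51, 4.37 and 5.26, and in the IAA list of CTCF it was 6.48. In the IAA lists of MBD2, MBD3 and TET1 the median fold was 1.93, 1.78 and 1.75, and 88.4%, 93.7% and 93% of regions had a fold under 3. The fold of a list depends on its depth, so these medians do not compare enrichment between lists.

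The lists also differed in depth. The background of the whole genome, recovered from fold and significance, was 4.35, 3.77, 4.72 and 5.68 fragments in the DMSO lists of CTCF, MBD2, MBD3 and TET1. Under BPK25 it was 5.89% of the DMSO value for CTCF, 49.5% for MBD2, 7.92% for MBD3 and 20.4% for TET1, and under IAA it was 21.6% for CTCF. For the IAA lists of MBD2, MBD3 and TET1 it came to 28.7%, 19.3% and 20.0%, but rested on 4, 1 and 2 regions. A shallower list can name fewer regions, so the region numbers above are not adjusted for depth.

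**Figure D1:**
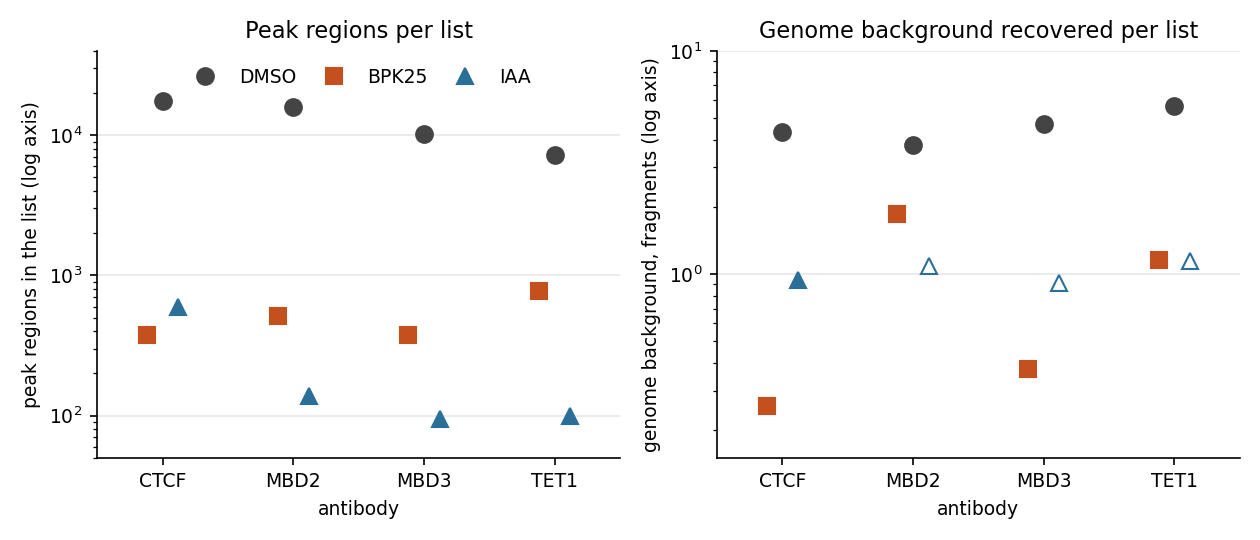
Number of peak regions per list (left) and recovered genome background in fragments (right), both on log axes, for each antibody under DMSO (circles), BPK25 (squares) and IAA (triangles); each point is 1 list called on 3 pooled replicates, and open symbols mark a background that rests on under 10 regions. All treated lists lie below the DMSO list of the same antibody in both panels, for CTCF at 375 and 595 regions against 17440.

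In DMSO, most regions of the NuRD subunits and of TET1 lay at CTCF regions. Of MBD2 regions, 73.5% (95% interval 72.8 to 74.2) overlapped a CTCF region, as did 80.0% (79.2 to 80.8) of MBD3 regions and 82.1% (81.2 to 83.0) of TET1 regions. Of the 17440 CTCF regions, 67.4% (66.7 to 68.0) had an MBD2 region, 46.4% (45.7 to 47.2) an MBD3 region and 33.9% (33.2 to 34.6) a TET1 region. All 4 proteins were listed at 4016 CTCF regions, which is 23.03%, and 4083 CTCF regions, or 23.4%, had none of the other 3. MBD2 was the only partner at 3660 CTCF regions, MBD3 at 940 and TET1 at 374.

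On chromosomes 1 to 22 and X, the shifted CTCF list met MBD2, MBD3 and TET1 regions at a mean of 0.314%, 0.192% and 0.138%, against 67.5%, 46.4% and 33.9% observed. None of 1000 shifts reached the observed share (one-sided permutation p = 0.001, the smallest they can give). The shifts place regions anywhere on a chromosome, so they do not set CTCF sites apart from other sites that can be enriched. The DMSO lists may also share the DMSO inputs as control, and no list of an unrelated antibody was analysed here.

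**Figure D2:**
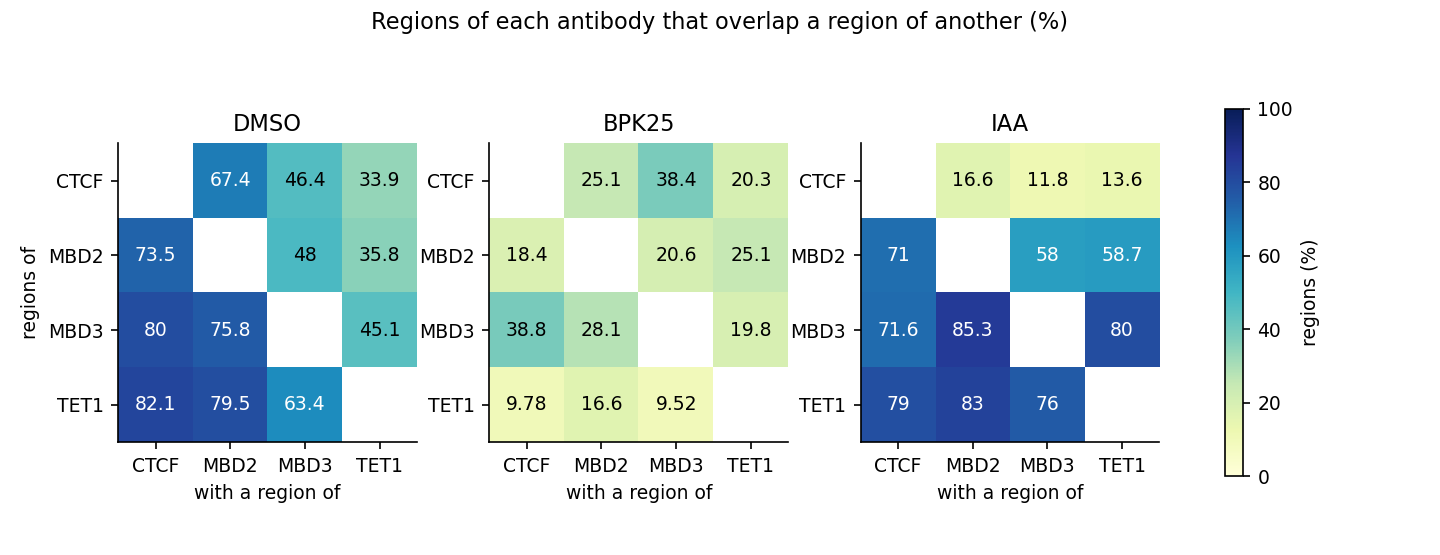
Percentage of the regions of each antibody (rows) that overlap a region of another antibody (columns) by 1 bp or more in the DMSO, BPK25 and IAA lists; the colour scale runs from 0 to 100%. In DMSO the CTCF column holds 73.5%, 80.0% and 82.1%, and under BPK25 the shares lie between 9.52% and 38.8%. The shares are not adjusted for the length or depth of the lists.

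CTCF regions of higher fold had a partner more often. From the lowest to the highest quartile of CTCF fold, the share with MBD2 went from 45.4% (43.9 to 46.9) to 86.8% (85.8 to 87.8). The share with MBD3 went from 28.8% to 70.6%, and that with TET1 from 18.9% to 57.2%. The median CTCF fold was 3.64 without a partner, 4.13 with 1, 4.54 with 2 and 5.31 with all 3. Each partner's list has its own detection limit, which these shares include.

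**Figure D3:**
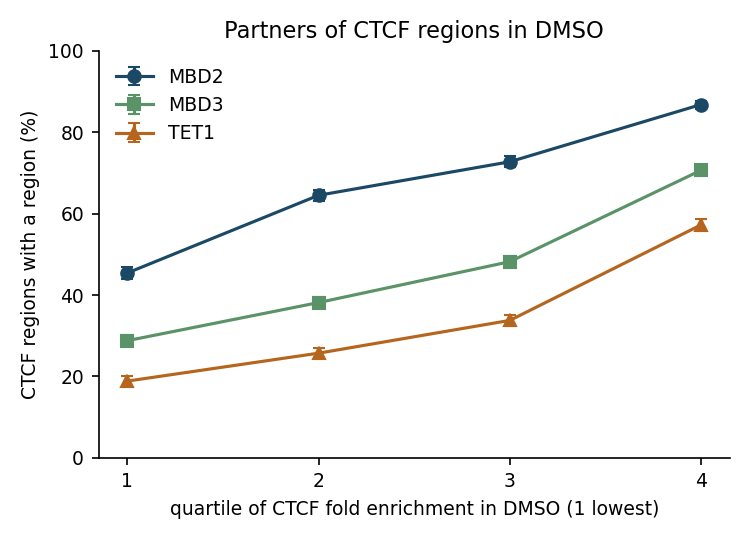
Percentage of DMSO CTCF regions with an MBD2 (circles), MBD3 (squares) or TET1 (triangles) region, by quartile of the authors' CTCF fold enrichment, 4360 regions each; bars are 95% Wilson intervals over regions. All 3 series rise from the lowest to the highest quartile, MBD2 from 45.4% to 86.8%.

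The strongest DMSO regions were common to the 4 antibodies and lay near chromosome ends. The region on chromosome 15 from 102519417 to 102520036 (hg19) had a CTCF fold of 24.96, and its MBD3 and TET1 folds were 15.4 and 12.6. On chromosome 9, a region from 11221 to 11614 had a CTCF fold of 24.3, and overlapping regions had folds of 21.2 for MBD2, 17.5 for MBD3 and 17.0 for TET1. The other MBD2 region of highest fold, at 19.4, lay on chromosome 16 from 60817 to 61238 and was also listed for CTCF, MBD2 and TET1 under BPK25.

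Under BPK25, a compound reported elsewhere to lower the amount of NuRD subunits, few DMSO regions were still listed. Of DMSO CTCF regions, 222 (1.27%, interval 1.12 to 1.45) overlapped a CTCF region under BPK25. The figures were 232 (1.45%, 1.28 to 1.65) for MBD2, 173 (1.71%, 1.47 to 1.98) for MBD3 and 498 (6.91%, 6.34 to 7.51) for TET1. The regions that were listed under BPK25 lay at DMSO regions of the same antibody in 59.5% of cases for CTCF, 46.5% for MBD2, 46.5% for MBD3 and 64.2% for TET1. Where only regions with a local background of at most 3 times the floor were kept, a filter chosen after seeing the data, the shares of DMSO regions with a BPK25 region were 0.237%, 0.711%, 0.248% and 4.79%.

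After shifting, 0.134% to 0.356% of BPK25 regions met a DMSO region on average, and none of 1000 shifts reached the observed share for any antibody. On chromosomes 1 to 22 and X, the observed shares were 51.0% for CTCF, 44.1% for MBD2, 40.5% for MBD3 and 64.0% for TET1. Positions drawn from the other 3 BPK25 lists gave 61.9%, 64.2%, 56.4% and 31.6%. The 752 TET1 regions make up much of the 1190 to 1322 positions available for CTCF, MBD2 and MBD3. Of these TET1 regions, 86.6%, 87.2% and 76.9% lay at DMSO CTCF, MBD2 and MBD3 regions, and the draw for TET1 lacks them. These draws thus follow the makeup of the lists, and no result per antibody is read from them. With a fold of 5 or more in every list, TET1 held 444 regions under BPK25 and 545 in DMSO, or 81.5%, where the full lists gave 10.8%. The fold of a list depends on its depth, so that threshold does not select alike in lists of different depth.

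TET1 regions under BPK25 lay mostly at regions of the DMSO lists. Of the 752 TET1 regions on chromosomes 1 to 22 and X, 86.6% overlapped a DMSO CTCF region and 87.2% a DMSO MBD2 region. The shares were 76.9% for DMSO MBD3 and 64.0% for DMSO TET1 regions, and 41 (5.45%) overlapped none of the DMSO lists. The DMSO lists differ in length, which these shares include. For CTCF, MBD2 and MBD3 under BPK25, 47.0%, 47.7% and 53.9% of regions overlapped no DMSO list. The TET1 region of highest fold at a DMSO region, at 17.7, lay on chromosome 9 from 998548 to 999012, and was listed for all 4 antibodies in both DMSO and BPK25. A region on chromosome 1 from 236877006 to 236878355 had the highest such CTCF fold, 12.4, and the overlapping MBD3 region had a fold of 10.6.

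Some regions under BPK25 had no DMSO region of the same antibody. The CTCF regions of highest fold of this kind lay on chromosome 13 from 114196280 to 114196623 (fold 11.1) and on chromosome 19 from 2938966 to 2939232 (fold 9.98), and neither was in any other list. For MBD2 they lay on chromosome 5 from 177482612 to 177483178 (fold 25.9) and from 55800500 to 55800920 (fold 22.7), both also listed for CTCF under IAA. The MBD3 region of this kind with the highest fold lay on chromosome 11 from 964910 to 965279 (fold 12.2), in no other list. For TET1 it lay on chromosome 4 from 178476223 to 178476457 (fold 11.1) and was a DMSO region of CTCF and MBD3. Recovered pileups were 13 and 12 fragments at these CTCF regions, 91 and 64 for MBD2, 17 for MBD3 and 26 for TET1. The CTCF and MBD3 folds thus rest on few fragments.

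Under IAA, an auxin used to remove proteins that carry a matching degron, few DMSO regions were still listed as well. DMSO regions with a region of the same antibody under IAA numbered 166 for CTCF (0.952%, 0.818 to 1.11), 98 for MBD2 (0.613%, 0.503 to 0.746), 75 for MBD3 (0.740%, 0.591 to 0.926) and 77 for TET1 (1.07%, 0.855 to 1.33). Split by their local background in the DMSO list, a step chosen after seeing the data, 103 of these CTCF regions, 87 MBD2, 59 MBD3 and 63 TET1 regions had over 3 times the floor. At most 3 times the floor was found for 41, 0, 1 and 1 of them, and for 22, 11, 15 and 13 the background was not recovered.

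The CTCF list under IAA differed in makeup from the other 3. Of its regions, 28.6% lay at a DMSO CTCF region, against 71.7%, 78.9% and 77% of MBD2, MBD3 and TET1 regions at DMSO regions of their own antibody. On chromosomes 1 to 22 and X, the shares were 25.05% for CTCF, 78.9% for MBD2, 93.0% for MBD3 and 88.3% for TET1. None of 1000 shifts reached them, and the shifted means were 0.135% to 0.381%. Positions drawn from the other 3 IAA lists gave 23.6% to 26.9% for MBD2, MBD3 and TET1. The 557 to 571 positions available came mostly from the 543 CTCF regions, so these draws largely restate the low share of that list. No such draw was made for CTCF, since the other lists held only 112 positions for 543 regions. Of the 543 CTCF regions under IAA on chromosomes 1 to 22 and X, 400 (73.7%) overlapped none of the DMSO lists and had a median fold of 7.97, against 2.56 for the others.

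The CTCF regions of highest fold under IAA lay on chromosome 5 from 177482576 to 177483186 (fold 70.4) and on chromosome X from 39646321 to 39647459 (fold 67.0), both without a DMSO region of any antibody and both also listed for MBD2 under BPK25. In all, 150 of the 400 regions recurred in that MBD2 list, and whether each of these lists holds only fragments of its own libraries is open, which bears on the shares kept in both. At DMSO CTCF regions, the highest folds were 16.6 on chromosome 11 from 18428806 to 18429350 and 14.9 on chromosome 6 from 7339162 to 7339781. A region on chromosome 17 from 19091350 to 19091577 had the highest MBD2 fold at a DMSO region under IAA, 6.01. It overlapped regions of 10 other lists, among them BPK25 MBD3 with a fold of 11.4 and IAA TET1 with a fold of 4.85. On chromosome 7 from 24039 to 24412, a TET1 region of fold 3.75 under IAA overlapped a region in all of the 11 other lists.

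Overlap between antibodies also differed by treatment. Under BPK25, 18.4% of MBD2, 38.8% of MBD3 and 9.78% of TET1 regions overlapped a CTCF region, and 47 CTCF regions (12.5%) had all 4 proteins. The BPK25 CTCF list held 375 regions at 5.89% of the DMSO background, against 17440 regions in DMSO. A shorter and shallower list leaves fewer regions to overlap, so these shares do not separate lost co-occupancy from list length and depth. Under IAA, 71.0% of MBD2, 71.6% of MBD3 and 79% of TET1 regions overlapped a CTCF region, while 11.8% to 16.6% of CTCF regions had one of the other 3. MBD3 and MBD2 under IAA overlapped in 85.3% of MBD3 regions. The interval of that share, from 81 of 95 regions, was 76.8% to 91.0%. The IAA lists of MBD2, MBD3 and TET1 had 31.2%, 40% and 40% of their regions off chromosomes 1 to 22 and X, and only 11, 4 and 3 regions with a local background of at most 3 times the floor, so their overlap is mostly one of regions with raised background.

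The share of DMSO regions still listed was largest in the highest quartile of DMSO fold for TET1 under BPK25, and in the lowest quartile for every other pair of antibody and treatment. On chromosomes 1 to 22 and X, TET1 regions with a BPK25 region made up 4.79% (3.89 to 5.90) of the lowest quartile of DMSO fold and 11.5% (10.1 to 13.0) of the highest. CTCF regions with a BPK25 region made up 1.58% (1.25 to 2.00), 0.184%, 0.2996% and 1.45% (1.14 to 1.86) from the lowest to the highest quartile. Under IAA, MBD2 gave 1.83% (1.46 to 2.302) in the lowest quartile and 0 of 3990, 0 of 3977 and 2 of 3982 regions above it. MBD3 and TET1 under IAA followed the same order, with 2.12% and 2.85% in the lowest quartile and at most 1 region in each of the others. Split by DMSO background, the lowest quartile no longer had the larger share under BPK25. Over 3 times the floor, the lowest and highest quartiles gave 5.55% and 15.02% for CTCF, 8.56% and 8.68% for MBD2, 10.2% and 13.6% for MBD3 and 12.1% and 48.8% for TET1. At most 3 times the floor they gave 0.235% and 0.611% for CTCF, 1.17% and 1.28% for MBD2, 0.0536% and 0.845% for MBD3 and 2.34% and 9.43% for TET1, with overlapping intervals for MBD2 in both sets and for CTCF and MBD3 in one of them. Under IAA, the lowest quartile kept the larger share over 3 times the floor for MBD2, MBD3 and TET1, while for CTCF it was 6.78% (5.25 to 8.72) against 4.72% (2.66 to 8.25), with overlapping intervals, and at most 3 times the floor only CTCF had any region on these chromosomes, 0.147% and 0.586%.

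**Figure D4:**
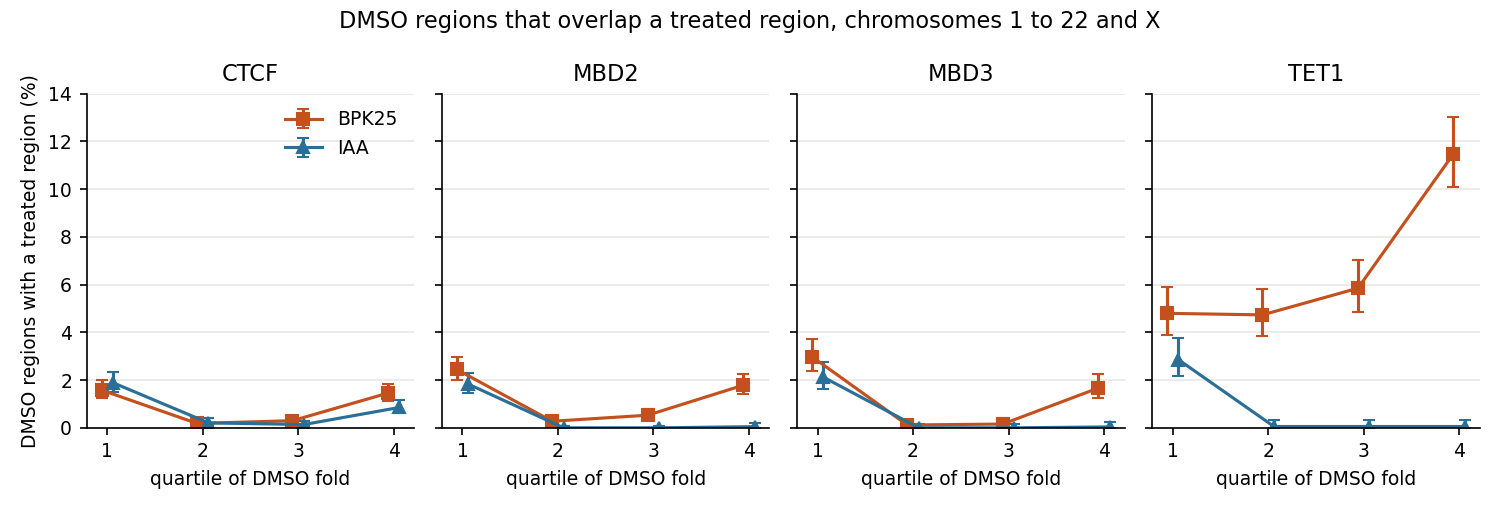
Percentage of DMSO regions on chromosomes 1 to 22 and X that overlap a region of the same antibody under BPK25 (squares) or IAA (triangles), by quartile of the DMSO fold enrichment; bars are 95% Wilson intervals over regions. TET1 under BPK25 reaches 11.5% in the highest quartile, while MBD2, MBD3 and TET1 under IAA lie near 0 above the lowest quartile.

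CTCF regions that had all 3 partners in DMSO were listed more often under treatment. Of CTCF regions with no partner in DMSO, 0.392% (0.241 to 0.636) had a CTCF region under BPK25, against 0.523% with 1, 0.641% with 2 and 3.78% (3.24 to 4.42) with all 3. Under IAA the shares were 0.147% (0.0674 to 0.320), 0.181%, 0.435% and 3.29% (2.78 to 3.88). The excess with all 3 partners was also present within the highest quartile of CTCF fold on chromosomes 1 to 22 and X, where 60 of 2038 regions with all 3 partners had a BPK25 region (2.94%, 2.29 to 3.77), against 1 of 302, 1 of 778 and 1 of 1216 with 0, 1 and 2. Within the lowest quartile it was 12.6% (9.61 to 16.4) of 373 regions with all 3 partners, against 0.219% of 1826 with none. In the quartiles between, few regions were kept and intervals overlap, for example 4 of 630 with all 3 partners against 0 of 1124 with none under BPK25, and 0.317% against 0.267% under IAA, in the second-lowest quartile. Regions of raised background make up most of those kept, 157 of 222 under BPK25 and 103 of 166 under IAA. Among CTCF regions of all chromosomes at most 3 times the floor, 0.0785% (0.0267 to 0.230) without a partner and 0.989% (0.705 to 1.39) with all 3 had a BPK25 region, and 0.105% (0.0407 to 0.269) and 0.869% (0.606 to 1.25) an IAA region. Over 3 times the floor, 5.02% (2.96 to 8.397) without a partner and 15.95% (13.3 to 18.96) with all 3 had a BPK25 region, and 0.772% (0.212 to 2.77) and 12.7% (10.4 to 15.5) an IAA region.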

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

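All tests in this part were chosen after the results were seen. Regions of mitochondrial DNA, which entered none of the comparisons on chromosomes 1 to 22 and X, numbered 4 in the CTCF list under IAA and 15, 15 and 15 in the MBD2, MBD3 and TET1 lists under IAA, against 0 in every DMSO and BPK25 list.

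A set of regions absent from DMSO recurred across both treatment and antibody. Of the MBD2 regions under BPK25 that overlapped no DMSO list, 71.0% were also CTCF regions under IAA, and of the 400 CTCF regions under IAA that overlapped no DMSO list, 37.5% (32.9 to 42.3) were also MBD2 regions under BPK25. The share was 50 of the 50 regions of highest CTCF fold, 93 of 100 and 133 of 200, and no other pair of lists with at least 50 such regions shared 10% or more. Of the 11 MBD2 regions under IAA that overlapped no DMSO list, 9 recurred for CTCF under IAA and 8 for MBD2 under BPK25, so the pattern is not limited to that pair of lists.

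Chance placement is argued against, since the largest share over 1000 shifts was 0.5%. Regions of many copies are argued against for the shared regions with a recovered background. Their median local background was 1.18 times the floor, below the 1.82 of DMSO CTCF regions. The background of the 2 regions of highest fold was not recovered. Fragments of one library carried over into the other remain a candidate explanation. Around 1 ratio of pileups the squared deviation was 1.05 times counting noise, against 6.09 with the heights shuffled. The deviation came only from regions that the MBD2 list also held, which leaves out MBD2 pileups under the threshold. It therefore does not decide between causes. The ratio was set on shared regions among the top 50, and 93 of the 100 regions of highest fold were shared. It would put 81 regions past the threshold with a probability above 0.95, and 75 of these were shared (92.6%). That share was therefore largely given beforehand. Over the 386 regions with a recovered pileup, 206 were predicted and 136 shared. The same values would come from a mislabelled library or from any source of one binding profile in both pools, and lists called on pooled replicates leave these cases open. No biological explanation was tested, since the design pairs neither these treatments nor these antibodies.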

How the results depend on the processing

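All treated lists stayed shorter than the DMSO list of the same antibody, and MBD2, MBD3 and TET1 kept that order at DMSO CTCF regions, under each alternative that was run for them. An overlap of 50% of the shorter region left every share within its 95% interval. The values that did move are percentages, and where 4 stand together they are for CTCF, MBD2, MBD3 and TET1. The cause of each move was not tested.

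With −log10 q of 5 or more in every list, region numbers as a percentage of DMSO were 1.15% for CTCF and 1.961% for MBD3 in BPK25. DMSO regions with a treated region came to 0.978% for CTCF, 0.959% for MBD2 and 5.94% for TET1 in BPK25. Treated regions with a DMSO region came to 85.5% for CTCF, 80.8% for MBD3 and 73.3% for TET1 in BPK25. DMSO CTCF regions with another region came to 69.5% for MBD2, 45.5% for MBD3 and 30.2% for TET1.

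With a fold enrichment of 5 or more in every list, region numbers as a percentage of DMSO were 7.31% for MBD3 and 81.5% for TET1 in BPK25, and 7.34%, 0.134%, 0.10995% and 0.183% in IAA. DMSO regions with a treated region came to 1.04% for CTCF, 0.790% for MBD2 and 18.5% for TET1 in BPK25, and 0.530%, 0.0168%, 0.0550% and 0% in IAA. Treated regions with a DMSO region came to 37.0%, 23.3%, 23.3% and 22.7% in BPK25, and 7.21%, 12.5%, 50% and 0% in IAA. DMSO CTCF regions with another region came to 64.2% for MBD2, 28% for MBD3 and 9.42% for TET1.

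On chromosomes 1 to 22 and X, region numbers as a percentage of DMSO were 0.569% for MBD3 and 0.840% for TET1 in IAA. DMSO regions with a treated region came to 0.875% for CTCF, 1.25% for MBD2 and 1.22% for MBD3 in BPK25, and 0.765%, 0.466%, 0.529% and 0.742% in IAA. Treated regions with a DMSO region came to 51.0% for CTCF and 40.5% for MBD3 in BPK25, and 25.05%, 78.9%, 93.0% and 88.3% in IAA.

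With summits within 150 bp in place of 1 bp of overlap, the percentages of DMSO regions with a treated region were 1.13% for MBD2 in BPK25, and 0.814% for CTCF in IAA. Treated regions with a DMSO region came to 52.8%, 35.5%, 40.4% and 59.2% in BPK25, and 23.9%, 60.9%, 65.3% and 63% in IAA. DMSO CTCF regions with another region came to 66.1% for MBD2, 45.4% for MBD3 and 32.8% for TET1.

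Without regions shared by all 4 antibodies, region numbers as a percentage of DMSO were 22.9% for TET1 in BPK25, and 0.620% for MBD3 in IAA. DMSO regions with a treated region came to 0.521%, 0.376%, 0.669% and 1.47% in BPK25, and 0.253%, 0.0751%, 0.114% and 0.157% in IAA. Treated regions with a DMSO region came to 18.7%, 9.02%, 11.2% and 6.05% in BPK25, and 5.71%, 6.52%, 7.37% and 5% in IAA. In both kinds of share only DMSO regions were left out, while the region numbers leave such regions out of both lists.

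Against as many DMSO regions of highest −log10 q as the treated list holds, the percentages of DMSO regions with a treated region were 27.5%, 12.4%, 28.6% and 26.0% in BPK25, and 14.8%, 18.1%, 31.6% and 34% in IAA. These need not be the regions of highest fold. Under IAA they were 88, 25, 30 and 34 regions, where the highest quartile of DMSO fold held 37, 2, 1 and 1 with a treated region. Under BPK25 they were 103, 63, 107 and 202, against 63, 71, 42 and 206 in that quartile.

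At a local background of at most 3 times the floor, a filter chosen after seeing the data, region numbers as a percentage of DMSO were 1.24% for CTCF and 2.22% for MBD3 in BPK25, and 0.0767% for MBD2, 0.0452% for MBD3 and 0.0475% for TET1 in IAA. DMSO regions with a treated region came to 0.237%, 0.711%, 0.248% and 4.79% in BPK25, and 0.2502%, 0%, 0.0113% and 0.0158% in IAA. Treated regions with a DMSO region came to 19.1%, 28.7%, 11.2% and 48.5% in BPK25, and 8.90%, 0%, 25% and 33.3% in IAA. DMSO CTCF regions with another region came to 65.5% for MBD2, 44.0% for MBD3 and 32.1% for TET1.

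The shares of treated regions at a fold of 5 or more rest on 8, 2 and 1 regions for MBD2, MBD3 and TET1 under IAA, and those at low background on 11, 4 and 3, with floors that rest on 4, 1 and 2 regions. Drawing positions from the other antibodies' regions gave no value for CTCF under IAA, since these were too few, nor for the partners of CTCF in DMSO, where list lengths fix the outcome. No paired analysis was possible because the lists were called on replicates 1 to 3 together, and for the same reason no replicate could be left out of them. A window of 5 kb around gene starts was not run, since no gene annotation of hg19 was used here. The recovered depth was lowest for CTCF under BPK25, at 5.89% of the DMSO background.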

Other observations

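All tests in this part were chosen after the results were seen, and the rule by which depth counts as argued against was made stricter after its values were seen. DMSO regions were densest on chromosomes 17 and 19 for all 4 antibodies, with 11.5 and 10.7 CTCF regions per Mb and 5.43 and 4.33 TET1 regions per Mb. They were sparsest on chromosomes 21 and 18, with 3.18 and 3.41 CTCF regions and 1.14 and 1.15 TET1 regions per Mb. These densities use the length up to the furthest region and include gaps of the assembly.

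DMSO regions that were listed under both treatments numbered 79 for CTCF, against 2.11 for independent sets of 222 and 166 regions. For MBD2, MBD3 and TET1 they numbered 51, 56 and 36, against 1.42, 1.28 and 5.32. Both treated lists are set against the same DMSO list, so part of the excess may come from that list, and many of these regions lay at raised background. The median local background of the regions kept under IAA was 37.8 times the floor for CTCF and 130.4, 138.7 and 122.8 times for MBD2, MBD3 and TET1, where all DMSO regions had 1.82 to 1.88. Restricting each list to at most 3 times the floor left 0.2502% of DMSO CTCF regions with an IAA region. In the window of chromosome 2 from 92000001 to 93000000 lay 17.9%, 24.6% and 18.3% of the MBD2, MBD3 and TET1 regions under IAA that lie on chromosomes 1 to 22 and X, and in that of chromosome 10 from 42000001 to 43000000 lay 15.8%, 21.1% and 15%. Of the 222 CTCF regions kept under BPK25, 71 lay off chromosomes 1 to 22 and X, 52 of them on 1 unlocalised contig of chromosome 9.

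That few DMSO regions were listed under treatment may follow from lower depth, from weaker enrichment or from lost occupancy. Where all fragments of a pool are taken as those of its labelled libraries, depth alone is argued against for MBD2 under BPK25 and CTCF under IAA, where thinning DMSO pileups to the treated background left 76.8% and 36.1% expected, against 1.42% and 0.816% observed, and the depth would have to be 29.2 and 19.8 times lower than the background shows (33.9% and 10.8% are expected at the widest difference in fragment length that the size selection allows). For CTCF, MBD3 and TET1 under BPK25 the expected shares were 6.05%, 7.40% and 26.6% against 1.17%, 1.55% and 6.83%. With that difference they become 1.76%, 1.97% and 7.75%, still above the observed intervals (1.02 to 1.34, 1.33 to 1.81 and 6.27 to 7.44). By the rule used, the background had to exceed the depth needed by over 4 times the size range of 2.5. At least 10 regions also had to lie at the floor. The background was only 3.52, 2.94 and 2.74 times the depth needed, so depth cannot be told apart there. For MBD2, MBD3 and TET1 under IAA the expected shares were 41.5%, 17.7% and 13.5% against 0.532%, 0.584% and 0.835%. With that difference in fragment length they become 11.7%, 3.92% and 2.76%, still above the observed shares. Depth cannot be told apart there because the floor rests on 4, 1 and 2 regions. For MBD3 and TET1 the background was also only 7.88 and 5.20 times the depth needed. The same pair of lists shares regions absent from DMSO, so fragments of another library in either pool stay open as a reason for few kept regions, as do weaker immunoprecipitation, a batch that coincides with the treatment and an effect of the treatment, none of which was tested.

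That MBD2, MBD3 and TET1 share CTCF regions in DMSO may reflect 1 enrichment profile common to the antibodies, or binding of all 4 proteins at the same sites. At shared regions of low background, MBD2, MBD3 and TET1 pileups kept 1 ratio to CTCF pileups with a squared deviation of 0.851, 0.840 and 0.870 times counting noise, against 3.84, 3.65 and 3.47 with the heights shuffled. In simulated lists, 1 common profile gave 0.908, and a site-to-site SD of 0.3 on the natural log scale 2.18. Of the regions that a common profile would put past the threshold with a probability above 0.95, only 73.3%, 55.4% and 45.6% were shared. Simulated lists gave 98.7% with 1 common profile, 95.6% at an SD of 0.3 and 83.4% at an SD of 0.6. The observed shares thus lay below every simulated setting, but only 1 ratio of pileups was simulated. The ratio and the deviation came only from regions that the partner list held, which leaves out partner pileups under the threshold and may raise the ratio. The simulated lists with an SD of 0 or 0.3 lost few such regions. Neither the observed deviations nor the observed shares can therefore be read against theirs. A common profile and separate binding cannot be told apart.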
